A study of Rattus norvegicus with 6 samples.

How the data were processed

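Libraries of poly-T selected RNA from 1 cm of femur around a fracture were analysed from 6 samples, 3 given gel only (Gel) and 3 given MgPA-Gel, grouped by their titles. Per the labels' protocols, 1.3 µg of RNA was used per library and fragments of 370 to 420 bp were selected; the kit's strandedness is not stated, so a gene cannot be told from an overlapping antisense gene. Per the submitters' processing notes, which give no roles, the authors used fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR 3.22.5. The genome build is not given in the sources used here.

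The authors deposited a table of gene counts, whole and not normalized, and a table of FPKM for the same 34538 genes. The count table had 46230 rows, of which 11692 were blank with no gene and no count other than 0, and these were left out. It also held 2 unnamed columns of group means, not used here. The one of MgPA-Gel matched the mean of the counts (tolerance 0.01) in all 34538 genes. The one of Gel matched in 19856 of 34538. Those matches can include the 12732 genes with a count of 0 in all 6 libraries, where a mean of 0 matches trivially. The deposited FPKM equals the count divided by gene length and by one library size per library of 14.5, 17.3, 13.7, 16.0, 16.0 and 17.0 M (mega) counts (Gel 1 to 3, then MgPA-Gel 1 to 3), which is not the library's total count. Of the genes, 12732 had a count of 0 in all 6 libraries and 1655 were assembled by the authors without a known name.

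Total counts ran from 13.6 to 18.2 M per library. The spread between libraries, beyond counting error, was a coefficient of variation of 41.3% at the common dispersion. This spread outweighs counting error in genes of many counts. Which of them limited the per-gene test in genes of few counts was not tested. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr left 14818 genes, TMM factors were used, and glmQLFit (robust) with glmQLFTest compared MgPA-Gel with Gel, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. CPM values use TMM-adjusted library sizes. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 42 lists, and again with an estimated correlation and with fry. A list's mean level was compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3. List members were matched by the name in the table, and 988 of 1033 symbols were found. The mean and the median of the members' log2 fold changes differ in sign for 4 of the 42 lists.

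The groups, lists, tests and the rule for named genes were set before the data were examined. The rule took, if no gene passed, the 6 genes of smallest unadjusted p in each direction with a symbol (not a LOC, clone, Ensembl or numeric name) and a mean log2 CPM of at least 1; from each list described, up to 4 members past the threshold or else of highest expression; and a fixed set of bone, cartilage, vessel and macrophage genes. Jun and Btg2 are named as members called over their list alone. Genes named outside the rule were chosen after their values were seen: LOC100912578, Asb12, Nhp2, Gpr84, Fam111a, Cxcl2, Csf3, Itgb3, Ocstamp and Oscar.

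The per-gene test was run on simulated counts made from these libraries' means and sizes, in 5 simulations. It called 49 of 72965 unchanged genes. The raised list of 25 genes at 2-fold was called in 5 of 5 with the preset correlation. It was called in 4 of 5 with an estimated one and 4 of 5 with fry, with 0 of 205 unchanged lists called. Simulated genes were drawn independently, whereas the estimated correlation was 0.23 in the immediate early list and 0.83 in the muscle fibre list. The 0 of 205 therefore does not measure false calls in the real lists. Other splits of the 6 real libraries put 8 to 21 lists past the preset-correlation threshold. Alternatives covered normalization factors, filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fold minimum, thresholds, a replicate block, protein-coding genes alone, removal of muscle and erythroid genes, a muscle covariate and each library left out. Chosen after seeing the data were removal of both libraries of high mitochondrial share, removal of the libraries at the ends of the muscle level, removal of mitochondrial genes, and the high mitochondrial share as a term.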

Results

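RNA was sequenced from the fracture site of female Sprague Dawley rats, an outbred laboratory stock, made osteoporotic by ovariectomy at 8 weeks of age. The left femur was osteotomized 12 weeks later and fixed with a nail of 1.2 mm, and 1 cm of femur around the fracture was taken for poly-T selected RNA. The tissue came from fractures given gel only (Gel, 3 libraries) and from fractures given MgPA-Gel (3 libraries), an adhesive hydrogel that the series title describes as built on plant phosphate coordination compounds. The time of harvest is not given in the sources used here, and the labels do not say whether the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Total gene counts, in M (mega) counts, were 16.2, 15.8 and 13.6 in Gel 1, 2 and 3 and 18.2, 15.4 and 15.4 in MgPA-Gel 1, 2 and 3. Per-gene values below are CPM (normalised counts per M counts) as mean ± SD with n = 3 per group, and log2 fold changes are MgPA-Gel over Gel ± SE.

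The comparison addresses how the fracture-site transcriptome differed when the adhesive carried MgPA, in a study whose title concerns bone homeostasis. Genes of bone formation lay at similar means in both groups. Runx2, the master transcription factor of the osteoblast lineage, was at 98.5 ± 25.4 CPM in Gel and 101 ± 22.4 in MgPA-Gel (log2 fold change 0.04 ± 0.27), and Alpl, the alkaline phosphatase of mineralizing cells, was at 473 ± 175 and 483 ± 70.9 (0.03 ± 0.30). Sp7, which acts downstream of Runx2, differed by 0.03 ± 0.39, and the matrix genes Ibsp, Spp1 and Bglap by -0.04 ± 0.40, -0.20 ± 0.43 and -0.17 ± 0.50. Col1a1, the main collagen chain of bone and the most abundant of these, had a lower mean in MgPA-Gel (49108 ± 15786 against 67724 ± 26531 CPM, log2 fold change -0.46 ± 0.48), within the spread of the libraries. Of the 21 measured members of the osteoblast and bone matrix list, 17 had a lower and 4 a higher mean in MgPA-Gel, with a median log2 fold change of -0.17, and the list was not past the threshold (camera adjusted p = 0.250). Without Gel 2 the list was past it toward lower values (adjusted p = 0.000270, in a range of 0.000270 to 0.879 over all settings), and with an estimated correlation it was past it in no setting (smallest adjusted p = 0.716). Its mean log2 fold change was -0.16, and turned to 0.19 without Gel 3 (adjusted p = 0.112) and 0.091 without Gel 3 and MgPA-Gel 1 (0.402). Sost, the Wnt antagonist made by osteocytes, stood at 1.85 ± 0.475 and 1.42 ± 1.67 CPM.

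Across all 14818 genes tested with edgeR's quasi-likelihood test, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.998. At an unadjusted p under 0.05 there were 389 genes, 264 higher and 125 lower in MgPA-Gel, against 741 that chance alone would give. DESeq2 on the same counts called 8 genes, 6 higher and 2 lower, and limma-voom called 0. In 1020 genes (6.88%) the 3 libraries of one group all lay above the 3 of the other, against the 10% that chance gives for 3 against 3. In simulated counts with the spread of these libraries, the test recovered 1.79%, 55.5% and 81.2% of genes changed 2-fold, 4-fold and 8-fold. The genes so changed numbered 335, 335 and 330 over 5 simulations, and the shares depend on such numbers because the adjustment does. Simulated genes were also drawn independently, whereas real genes can vary together. The shares may therefore differ from the power of the real comparison.

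Genes were ranked among those with a mean log2 CPM of at least 1 and a symbol other than a LOC, clone or identifier name. Of these, Slc7a11, Ccn1, Mill1, Egr1, Cystm1 and Ier3 had the smallest unadjusted p on the higher side. On the lower side they were Vegfd, Ecm2, Hap1, Slc2a3, Abca4 and Pla2g2d. None was past the edgeR threshold (each adjusted p = 0.998). Slc7a11 (ENSRNOG00000010210, chromosome 2, 139453774 to 139528162), the cystine-importing subunit of the cystine/glutamate exchanger, was at 3.23 ± 1.55 CPM in Gel and 16.5 ± 2.80 in MgPA-Gel, a log2 fold change of 2.34 ± 0.42. Ccn1 (ENSRNOG00000014350, chromosome 2, 251529354 to 251532312), a matricellular protein induced by growth factors and mechanical load, was at 143 ± 8.89 and 262 ± 20.3 CPM (0.87 ± 0.16). Vegfd (ENSRNOG00000003587, chromosome X, 31816436 to 31851715), a lymphangiogenic growth factor, was at 11.9 ± 3.71 and 3.71 ± 0.626 CPM (-1.67 ± 0.32). DESeq2 called these 3 genes, with adjusted p = 0.00170 for Slc7a11, 0.0228 for Ccn1 and 0.0345 for Vegfd. Mill1 differed by 2.10 ± 0.43, Cystm1 by 1.03 ± 0.24, and on the lower side Ecm2, a matrix protein, by -2.32 ± 0.56 and Slc2a3, a neuronal-type glucose transporter, by -2.52 ± 0.67. Hap1, Abca4 and Pla2g2d, a secreted phospholipase, differed by -1.56 ± 0.41, -1.47 ± 0.40 and -1.47 ± 0.40. Coordinates are those of the deposited table, whose genome build is not given in the sources used here.

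**Figure D1:**
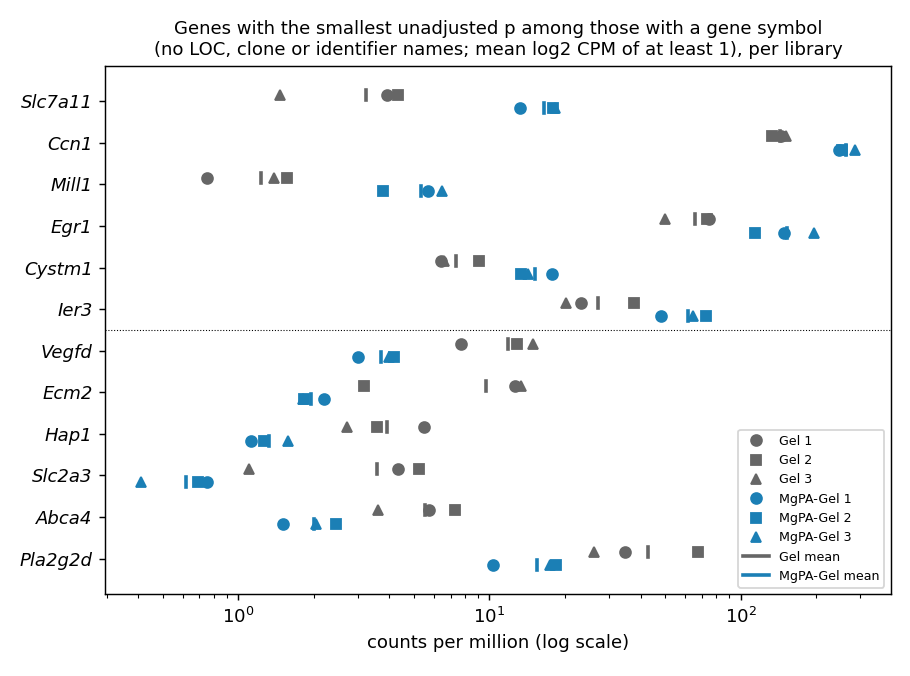
CPM (log axis) in each of the 6 libraries for the 6 genes with the smallest unadjusted p on the higher side (above the dotted line) and on the lower side (below it). Genes were taken from those with a mean log2 CPM of at least 1 and a symbol other than a LOC, clone or identifier name. Symbols are libraries and short vertical bars are group means. Slc7a11 lay at 1.47 to 4.33 CPM in the Gel libraries and at 13.2 to 18.2 in the MgPA-Gel libraries. None of these genes passed the edgeR threshold.

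Immediate early genes, which cells switch on within minutes of growth factor, cytokine or mechanical stimulation, were higher in MgPA-Gel as a group. Of 25 measured members 20 had a higher mean, with a median log2 fold change of 0.87, and camera with its preset correlation put the list past the threshold (adjusted p = 1.12e-08; adjusted p = 0.832 with an estimated correlation). The mean log2 fold change of the list was 0.77, and 0.39 without MgPA-Gel 2 (adjusted p = 0.000250, range 3.24e-10 to 0.000250). No member passed over all genes tested, while 5 did when adjusted over the list alone: Ccn1, Egr1, Ier3, Btg2 and Jun, all higher. That adjustment was made within each list and takes no account of the 42 lists examined. Egr1, a zinc-finger transcription factor, was at 66.1 ± 14.0 CPM in Gel and 153 ± 41.5 in MgPA-Gel, Jun, an AP-1 subunit, at 141 ± 15.8 and 224 ± 29.7, and Btg2, an antiproliferative gene, at 47.0 ± 11.2 and 117 ± 47.5. In 12 members the groups did not overlap, 11 of them higher in MgPA-Gel. Chance gives 10% of genes, and over all genes tested the share was 6.88%. The members vary together (estimated correlation 0.23), so they are not independent draws to set against either share. Ccn2, the relative of Ccn1 known as connective tissue growth factor, went the other way (565 ± 325 against 265 ± 33.8 CPM, log2 fold change -1.09 ± 0.40), with Gel 3 at 934 CPM beside 437 and 322 in Gel 1 and 2. Without Gel 3 its log2 fold change was -0.53. The mean of Zfp36, which destabilizes cytokine mRNA, rested mostly on 1 library, with 1373 CPM in MgPA-Gel 2 beside 133 and 140 in MgPA-Gel 1 and 3. The mean level of the list was higher in all 3 MgPA-Gel libraries than in all 3 Gel libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The margin was narrow, with MgPA-Gel 1 at -0.11 beside Gel 2 at -0.16, and the level was highest in MgPA-Gel 2 (0.79), which also had the highest inflammatory macrophage level.

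Of 42 gene lists fixed before the data were examined, 15 passed the preset-correlation threshold, 9 toward higher and 6 toward lower values in MgPA-Gel. With an estimated correlation 0 passed (smallest adjusted p = 0.832), and fry, which tests each list on its own, gave 0 (smallest adjusted p = 0.975), with 0 lists at an unadjusted p under 0.05 in either. Among the 42 lists, 2 had mean levels that did not overlap between groups, immediate early genes and inositol phosphate metabolism, where chance gives 10%. Pan-macrophage, complement and coagulation, and muscle regeneration genes were among those toward higher values (adjusted p = 0.0113, 0.0289 and 0.0474; adjusted p = 0.832, 0.845 and 0.832 with an estimated correlation). These calls held in 16, 15 and 13 of 20 settings with the preset correlation. Their median log2 fold changes were 0.27, 0.28 and 0.93. The first 2 lists had their highest level in MgPA-Gel 2 (0.43 and 0.55), while muscle regeneration was high in MgPA-Gel 1 and 3 (1.53 and 1.24) and below Gel 1 and Gel 2 in MgPA-Gel 2 (-0.72).

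Skeletal muscle transcripts showed the widest spread. All 31 measured members of the muscle fibre list had a higher mean in MgPA-Gel, with a median log2 fold change of 5.18 (adjusted p = 5.27e-10; adjusted p = 0.832 with an estimated correlation), but the libraries of the 2 groups overlapped. The mean log2 fold change of the list was 4.53, and 1.42 without MgPA-Gel 1 (adjusted p = 0.0117). Without Gel 3 and MgPA-Gel 1 it was 0.94 and not past the threshold (adjusted p = 0.855, in a range of 2.48e-20 to 0.855 over all settings). The list took 5.36% of counts in MgPA-Gel 1, 0.370% in MgPA-Gel 3 and 0.107% in MgPA-Gel 2, beside 0.156%, 0.158% and 0.132% in Gel 1, 2 and 3. Acta1, skeletal muscle actin, was at 8042 CPM in MgPA-Gel 1, 571 in MgPA-Gel 3 and 18.0 in MgPA-Gel 2, and at 152, 84.7 and 1.47 in the Gel libraries. Myh1, a fast myosin heavy chain, and Myl1, a fast myosin light chain, followed the same order of MgPA-Gel libraries. The near-equal shares of Gel 1, 2 and 3 do not show equal muscle content. Myh1 was at 116, 42.1 and 0.366 CPM there and the list level at -0.15, -0.48 and -3.89, while Tpm1, another member, was at 582, 520 and 856 CPM. Nuclear genes of oxidative phosphorylation were also highest in MgPA-Gel 1 (list level 0.78, against -0.45 to 0.08 in the other 5 libraries). That list was past the threshold toward higher values (36 of 38 members, median log2 fold change 0.30, adjusted p = 0.00170; adjusted p = 0.874 with an estimated correlation), with Atp5f1b, a subunit of ATP synthase, at 818 ± 167 and 1007 ± 363 CPM. With the muscle fibre level as a covariate its mean log2 fold change turned from 0.37 to -0.20, past the threshold toward lower values (adjusted p = 0.000283), as it was without Gel 3 and MgPA-Gel 1 (-0.15, adjusted p = 0.0158). It was -0.037 without MgPA-Gel 1 and 0.61 without MgPA-Gel 2. The list was not past the threshold without MgPA-Gel 1 (adjusted p = 0.272), without Gel 3 (0.152) or without Gel 1 and MgPA-Gel 1 (0.651), in a range of 4.78e-12 to 0.651 over all settings. With an estimated correlation it was past it in no setting (smallest adjusted p = 0.771). Genes on the mitochondrial chromosome took 24.0% of counts in Gel 1 and 25.9% in MgPA-Gel 1, beside 8.64% and 8.83% in Gel 2 and 3 and 5.29% and 6.10% in MgPA-Gel 2 and 3; each 95% exact Clopper-Pearson interval was narrower than 0.05 percentage points and covers counting error only.

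**Figure D2:**
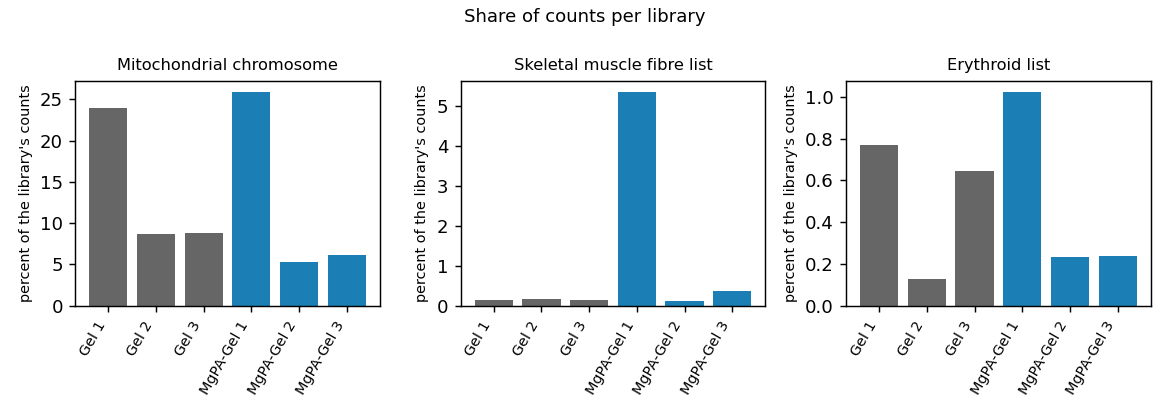
Percent of each library's counts from the mitochondrial chromosome, the skeletal muscle fibre list and the erythroid list, 1 bar per library, Gel in grey and MgPA-Gel in blue; each panel has its own axis from 0. Gel 1 and MgPA-Gel 1 had mitochondrial shares of 24.0% and 25.9%, and MgPA-Gel 1 alone had a muscle fibre share above 1%.

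Neutrophil, inflammatory macrophage, and T and NK cell lists were past the threshold toward higher values in MgPA-Gel, unevenly between libraries. Of 20 neutrophil genes 19 had a higher mean (median log2 fold change 1.16, adjusted p = 0.000380; adjusted p = 0.832 with an estimated correlation). S100a8 and S100a9, the calprotectin subunits of neutrophils, were at 48.1 ± 26.8 and 87.4 ± 60.1 CPM in Gel and at 318 ± 281 and 562 ± 595 in MgPA-Gel. In MgPA-Gel 3 they were at 56.1 and 85.6 CPM, below Gel 1 and Gel 2, and the list level there (-0.70) was also below both, beside 1.03 and 1.28 in MgPA-Gel 1 and 2. The neutrophil list was not past the threshold without MgPA-Gel 1 (adjusted p = 0.132), with the muscle fibre level as a covariate (0.0533) or without Gel 3 and MgPA-Gel 1 (0.306), in a range of 3.11e-08 to 0.306 over all settings. Its mean log2 fold change was 1.54, and 0.82 without MgPA-Gel 2. Inflammatory macrophage genes had a higher mean in 18 of 20 (median 0.96, adjusted p = 0.00163; adjusted p = 0.832 with an estimated correlation), and the list level was highest in MgPA-Gel 2. Il1b, the inflammasome-processed cytokine, was at 895 CPM in MgPA-Gel 2, 62.3 in MgPA-Gel 1 and 40.4 in MgPA-Gel 3, and at 10.4, 64.8 and 3.74 in the Gel libraries. Socs3, a feedback inhibitor of cytokine signalling, was at 1316 CPM in MgPA-Gel 2 and at 40.8 to 118 in the other 5 libraries, and without MgPA-Gel 2 its log2 fold change went from 2.72 to -0.058. The inflammatory list was not past the threshold without MgPA-Gel 2 or without Gel 3 (adjusted p = 0.361 and 0.112, in a range of 1.65e-05 to 0.361 over all settings). Its mean log2 fold change was 1.18, and 0.32 without MgPA-Gel 2. All 17 T cell and NK cell genes had a higher mean (median 0.38, adjusted p = 0.000752; adjusted p = 0.832 with an estimated correlation), with Cd4 at 93.3 ± 5.06 and 106 ± 52.7 CPM. Cd4 was at 69.9 and 81.6 CPM in MgPA-Gel 1 and 2, below the Gel libraries (87.6 to 97.3), and at 166.5 in MgPA-Gel 3. Which cells made Cd4 was not tested. Cd8a, Tcf7 and Lck, also among the members of highest expression, had log2 fold changes of 0.29 ± 0.51, 0.25 ± 0.26 and 0.03 ± 0.30. The level of the T cell and NK cell list was higher in Gel 2 (0.41) than in MgPA-Gel 1 and 3 (0.15 and 0.05). The mean log2 fold change of that list was 0.61, and 1.38 without Gel 2. Mrc1 and Arg1, markers of reparative macrophages, differed by 0.09 ± 0.39 and 0.79 ± 0.57. Tnf, the inflammatory cytokine, had 0 to 2 counts per library and was not tested.

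Mast cell, B cell, cell cycle and ribosome lists were past the threshold toward lower values in MgPA-Gel. Of 10 mast cell and basophil genes 9 had a lower mean (median log2 fold change -1.33, adjusted p = 4.15e-06; adjusted p = 0.832 with an estimated correlation), with Cma1, mast cell chymase, at 29.1 ± 17.8 and 8.57 ± 3.67 CPM and Cpa3, mast cell carboxypeptidase, at 27.2 ± 17.5 and 11.7 ± 3.70. Gel 1 lay with the MgPA-Gel libraries for both genes, at 8.70 and 6.99 CPM. Of 34 cell cycle genes 28 had a lower mean, by a small amount (median -0.23, adjusted p = 4.15e-06; adjusted p = 0.832 with an estimated correlation). The mean log2 fold change was -0.20, and -0.072 without Gel 1 (adjusted p = 0.0421, range 1.08e-08 to 0.0421) and -0.35 with the muscle fibre level as a covariate. Mki67, the proliferation marker, was at 85.7 ± 21.4 and 68.1 ± 15.3 CPM and Top2a, the topoisomerase of dividing cells, at 70.2 ± 7.60 and 60.9 ± 5.42. Of 46 cytosolic ribosome genes 41 had a lower mean (median -0.15, adjusted p = 0.000115; adjusted p = 0.874 with an estimated correlation), with Rplp0 at 2271 ± 400.2 and 1844 ± 75.8 CPM. Of 15 B cell and plasma cell genes 11 had a lower mean (median -0.36, adjusted p = 0.0107; adjusted p = 0.832 with an estimated correlation), with Ebf1, a B lineage transcription factor also made by stromal cells, at 61.4 ± 21.7 and 38.8 ± 6.77. Sdc1, Xbp1 and Blnk, also among the B cell list members of highest expression, differed by 0.26 ± 0.35, 0.08 ± 0.26 and -0.02 ± 0.32. The ribosome list was not past the threshold without Gel 1 or MgPA-Gel 2 (adjusted p = 0.113 and 0.247, range 3.15e-16 to 0.247). Its mean log2 fold change was -0.13. It was -0.017 without Gel 1, -0.24 without Gel 3 or without MgPA-Gel 1, and -0.35 with the muscle fibre level as a covariate. The B cell list was not past it without Gel 2, Gel 3 or MgPA-Gel 3 (0.0734, 0.0716 and 0.403, range 4.85e-08 to 0.403). Its mean log2 fold change was -0.38. It was -0.073 without Gel 3, -0.22 without MgPA-Gel 3 and -0.26 without Gel 2, and -0.69 without Gel 1, -1.07 without MgPA-Gel 1 and -1.32 without both.

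The osteoclast list was not past the threshold, and several of its genes differed widely among the MgPA-Gel libraries. In 1 of 19 members, Oscar, an osteoclast-associated receptor, the groups did not overlap (6.89 to 12.5 CPM in Gel and 15.5 to 63.7 in MgPA-Gel). Chance gives 10%, and over all genes tested the share was 6.88%. Oscar was highest in MgPA-Gel 2, the library with the lowest osteoclast list level (-0.91). Ctsk, the collagen-degrading protease of osteoclasts, was at 10837 CPM in MgPA-Gel 3, 5261 in MgPA-Gel 1 and 1470 in MgPA-Gel 2, against 5037 ± 996 in Gel (log2 fold change 0.22 ± 0.65). Acp5, the tartrate-resistant phosphatase, was at 3730, 2966 and 473 CPM in the same order, against 2752 ± 405 (-0.20 ± 0.67), and Mmp9, a gelatinase, at 3627, 1088 and 610, against 1452 ± 472 (0.29 ± 0.66). Of the 19 members 12 had a higher mean (median 0.13, adjusted p = 0.929, with the test leaning to lower values). The list was past the threshold toward higher values without MgPA-Gel 2 (adjusted p = 0.0270) and toward lower values without MgPA-Gel 3 (9.39e-05, in a range of 9.39e-05 to 0.974 over all settings). With an estimated correlation it was past it in no setting (smallest adjusted p = 0.879). Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, was at 20.5 CPM in MgPA-Gel 2 and at 0 to 9.18 in the other 5 libraries, and its decoy receptor Tnfrsf11b differed by 0.22 ± 0.33. The list of RANKL, osteoprotegerin and related signals had a higher mean in 8 of 10 members and was not past the threshold (adjusted p = 0.0853). It was past it in 4 of 20 settings with the preset correlation, among them without Gel 1, without Gel 2 and with no filter on low counts (0.0173, 0.0246 and 0.0404, range 0.00802 to 0.378). With an estimated correlation it was past it in 0 of 20 (smallest adjusted p = 0.602). Its mean log2 fold change was 0.96. It was 0.10 without MgPA-Gel 2, 1.59 without Gel 1, 2.10 without Gel 2 and 1.49 with no filter.

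Fibrillar collagen and matrix genes had a lower mean in 24 of 32 members (median log2 fold change -0.27, adjusted p = 0.00261; adjusted p = 0.874 with an estimated correlation). Col3a1, the collagen of early callus and soft tissue, was at 23593 ± 7707 and 16764 ± 10053 CPM, and Fn1, fibronectin, at 7122 ± 2723 and 3942 ± 2123. MgPA-Gel 1, the library with the highest muscle share, had the lowest level of both. With the muscle fibre level as a covariate the list's mean log2 fold change turned from -0.25 to 0.23, past the threshold toward higher values (adjusted p = 0.00563), as it was without Gel 3 and MgPA-Gel 1 (0.24, adjusted p = 0.00483). Without MgPA-Gel 1 or Gel 3 it was -0.0080 and 0.0029, and without MgPA-Gel 2 it was -0.54. The list was not past the threshold without MgPA-Gel 1 (adjusted p = 0.855), without Gel 3 (0.589) or without Gel 1 and MgPA-Gel 1 (0.489, range 5.31e-07 to 0.855). With an estimated correlation it was past it in no setting (smallest adjusted p = 0.717). Cartilage genes varied widely between libraries: Col2a1, the collagen of cartilage, was at 109 CPM in MgPA-Gel 1 and 0.347 in Gel 2 (log2 fold change 0.23 ± 1.58), Sox9, the chondrocyte transcription factor, differed by -0.45 ± 0.40, and Col10a1, of hypertrophic cartilage, had 289 counts in MgPA-Gel 1, 141 in Gel 3 and 1 to 4 elsewhere, too few libraries to be tested. The cartilage list was not past the threshold (adjusted p = 0.929).

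Magnesium channels and transporters were not past the threshold (8 of 14 members with a higher mean, median log2 fold change 0.05, adjusted p = 0.790). Trpm7, a magnesium-permeable channel kinase, was at 53.1 ± 4.52 and 52.2 ± 10.1 CPM. Vegfa, the main angiogenic growth factor, had a higher mean in MgPA-Gel (76.1 ± 39.1 and 141 ± 35.5 CPM, log2 fold change 0.88 ± 0.42), not past the threshold. Endothelial genes had a lower mean in 23 of 26 members (median -0.18, adjusted p = 0.0362; adjusted p = 0.874 with an estimated correlation), a call that held in 13 of 20 settings with the preset correlation. The endothelial list level was 0.14, 0.39 and -0.35 in Gel 1, 2 and 3 and -0.12, 0.07 and -0.13 in MgPA-Gel 1, 2 and 3. Gel 3 thus lay below every MgPA-Gel library. Pecam1 was not matched by name, and a gene without a symbol that the table describes as PECAM-1 (chromosome 10, 94850971 to 94886250) differed by -0.32 ± 0.21.

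**Figure D3:**
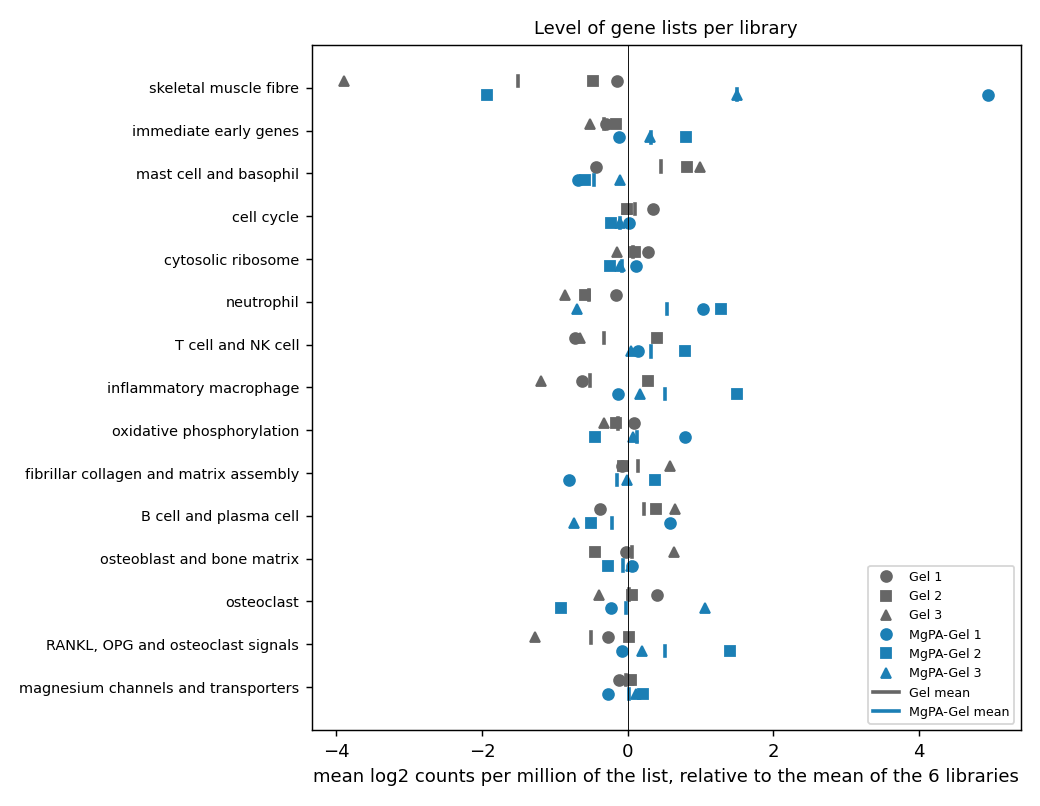
Mean log2 CPM of 15 gene lists in each library, relative to the mean of the 6 libraries; symbols are libraries and short vertical bars are group means. Muscle fibre genes ranged from -3.89 in Gel 3 to 4.95 in MgPA-Gel 1, osteoclast genes from -0.91 in MgPA-Gel 2 to 1.06 in MgPA-Gel 3, and of the lists drawn, immediate early genes alone had all 3 MgPA-Gel libraries above all 3 Gel libraries.

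Whole transcriptomes correlated at 0.935 to 0.952 between Gel libraries, 0.847 to 0.931 between MgPA-Gel libraries and 0.861 to 0.964 between groups (Pearson correlation across genes, which are not independent replicates). The first principal component of the 500 most variable genes held 54.8% of their variance and set MgPA-Gel 1 (72.1) apart from the other libraries (-37.5 to 10.9), and 21 of its 50 genes of highest weight were muscle fibre genes.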

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

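The settings that leave out Gel 1 with MgPA-Gel 1, leave out Gel 3 with MgPA-Gel 1, drop mitochondrial genes or add the mitochondrial share as a term were chosen after seeing the data. The count of genes called was 0 with edgeR (389 at an unadjusted p under 0.05) and in every setting but 2: DESeq2 called 8, and leaving out 1 library in turn gave 0 to 2, the 2 being Nhp2 and Fam111a without MgPA-Gel 2. The count of lists past the threshold was 15, and 9 to 20 with 1 library left out (9 without Gel 3, 20 without Gel 2); it was 0 with an estimated correlation and 0 with fry. Immediate early genes, T and NK cells, mast cells and cell cycle kept their direction and side in 20 of 20 settings with the preset correlation, with mean log2 fold changes of 0.39 to 0.94, 0.43 to 1.38, -1.38 to -0.75 and -0.36 to -0.072. With the muscle fibre level as a covariate the mean log2 fold change was 0.040 for the muscle fibre list, which that covariate removes by construction, -0.20 for oxidative phosphorylation and 0.23 for fibrillar collagen, and that of the genes Acta1, Myl1 and Tpm1 was -0.27, -0.42 and -0.14. Without Gel 3 and MgPA-Gel 1 it was -0.15 for oxidative phosphorylation, 0.24 for fibrillar collagen and -0.0092 for Tpm1, and without Gel 1 and MgPA-Gel 1 it was -0.33 for Tpm1. With 1 library left out, the ranges were -0.037 to 0.61 for oxidative phosphorylation, -0.54 to 0.0029 for fibrillar collagen, -0.48 to 0.51 for osteoclast genes, -0.38 to 0.19 for osteoblast genes, -0.23 to 2.16 for Tpm1, -0.058 to 3.26 for Socs3 and -0.063 to 0.74 for Slc41a1, a magnesium transporter; the cause was not tested. Of 2095 values of 81 named genes under the alternatives, 146 changed sign, 138 of them within 1 SE of 0 and not counted as reversals. The labels do not say that replicate numbers pair samples. Deviations from the group means correlated at 0.25, 0.20 and -0.03 for same-numbered libraries and at -0.29 to 0.06 for differently numbered ones. The pairs numbered 1 and 2 were thus the highest, and whether a shared factor underlies them was not tested. A replicate block gave 0 genes (464 at an unadjusted p under 0.05, smallest adjusted p 0.261). It gave 20 lists, the RANKL signals list among them (adjusted p = 0.00802, range 0.00802 to 0.378). Depth limits the genes of few counts: Tnf, with 0 to 2 counts per library, could not be tested.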

Other observations

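The MgPA-Gel libraries each had the highest level of some genes or lists, picked after their values were seen. Across all genes tested MgPA-Gel 3 lay close to Gel 2 (Pearson correlation 0.964). MgPA-Gel 2 had the highest neutrophil chemokine and growth factor levels, with Cxcl2 at 146 CPM and Csf3 at 42.9, beside at most 9.31 and 2.13 in the other 5 libraries. MgPA-Gel 3 had the highest levels of Itgb3, the osteoclast integrin, at 349 CPM (56.5 to 136 elsewhere) and of Ocstamp, a fusion gene of osteoclast precursors, at 43.9 (4.35 to 19.6 elsewhere). The mean level of the erythroid list was highest in MgPA-Gel 1 and Gel 1 (2.31 and 2.18) and lowest in Gel 2 (-2.84), an order that single erythroid genes need not follow.

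Some genes differed in steps of several-fold between libraries. LOC100912578, an lincRNA on chromosome 3 (74226407 to 74229066), had the smallest p of all genes tested (0.000115 in edgeR; DESeq2 adjusted p = 3.35e-10), with 14, 44 and 14 counts in Gel and 357, 230 and 295 in MgPA-Gel. Nhp2, a small nucleolar RNP protein, had 18, 15 and 12 counts in Gel and 487, 8 and 396 in MgPA-Gel, and Fam111a, a protease gene, 303, 273 and 265 against 2886, 156 and 4368. The other genes DESeq2 called outside the named set included Asb12 (0, 0 and 0 against 118, 2 and 30 counts) and Gpr84, a receptor of activated myeloid cells (6, 14 and 6 against 76, 227 and 26). Among the MgPA-Gel libraries, Asb12 and Nhp2 had the same order as Acta1 (highest in MgPA-Gel 1, lowest in MgPA-Gel 2). Gpr84 had the same order as Il1b (highest in MgPA-Gel 2, lowest in MgPA-Gel 3). So few libraries can share an order by chance. Whether tissue content or sequence differences between outbred animals enter such steps was not tested.

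Of the tests that follow, all but the count of lists over other splits were chosen, with their bounds, after the result was seen. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes, as large a result as in 10 of 10 splits by definition, and the highest other split called 1. For lists past the threshold, 5 of 10 splits gave at least the real 15, with 21 as the highest other. That split set Gel 1, Gel 3 and MgPA-Gel 1 against the rest, and gave 1483 genes at an unadjusted p under 0.05 beside 389 for the real one. The erythroid list level divided the libraries in the same way, at 2.18, 1.04 and 2.31 in Gel 1, Gel 3 and MgPA-Gel 1 and at -2.84 to -1.25 in the rest. Whether blood or marrow content underlies that split was not tested.

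Muscle fibre transcripts were highest in MgPA-Gel 1. Muscle carried over with the bone block stays open and was not tested on values other than the fibre genes themselves. A difference between treatments stays open too, with an exact permutation p of 0.3 for the list level, and MgPA-Gel 2 lay below Gel 1 and Gel 2.

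Immediate early genes were higher in MgPA-Gel by 0.65 in mean list level. With the muscle level as a covariate the difference was 0.88 ± 0.30 (SE), and in the 4 libraries outside the 2 of high mitochondrial share it was 0.89 ± 0.30. Both bounds were set at 1 SE and would not have been met at 2 SE. MgPA-Gel 1, highest in muscle level (4.95), had the lowest immediate early level of its group (-0.11). Adjusting for muscle or leaving out the 2 libraries therefore had to raise the difference, so neither test decides. Without MgPA-Gel 2 the list's mean log2 fold change went from 0.77 to 0.39. Handling between tissue removal and lysis, which can induce these genes, cannot be told apart from the treatment: the heat shock list had a median log2 fold change of 0.028 (adjusted p = 0.929), and heat shock genes need not follow handling. The treatment may also act on these genes, which was not tested separately.

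Gel 1 and MgPA-Gel 1 had a high mitochondrial share. Muscle is argued against in Gel 1, where the fibre list took 0.156% of counts beside an excess of 15.3 percentage points over Gel 2 and 3, and stays open in MgPA-Gel 1 (5.36% beside 20.2 points). Red marrow or blood stays open: the same 2 libraries had the highest erythroid level, but Gel 3, with an erythroid share of 0.646% beside 0.768% in Gel 1, had a ratio of mitochondrial to erythroid share 2.29 times smaller. A shared batch is also open, as the labels name none.

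A hypothesis that Slc7a11 was higher as part of a wider Nrf2 response found no positive evidence: the other 22 tested members of the Nrf2 list had a median log2 fold change of 0.029, with 12 of them above 0, and members going both ways leave a response of some of them possible.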
